A study of Bos taurus with 78 samples.

How the data were processed

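Skin biopsies of 39 Braford cattle (Bos taurus), 20 classed in the labels as tick resistant and 19 as susceptible, were sampled before and 24 h after infestation, which gave 78 libraries. Per the labels' protocols, total RNA was made into libraries individually with the TruSeq RNA kit v2, a kit that does not mark the strand, and sequenced in paired-end mode on an Illumina HiSeq1500. Per the submitters' processing notes, FastQC 0.11.8, HISAT2 2.1.0, SAMtools 1.9, featureCounts 1.6.4 and DESeq2 were used with the bovine genome ARS-UCD1.2. The roles and settings of these tools are not given in the sources used here.

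The deposited count table, made by the authors with featureCounts per the file headers, holds whole-number read counts for 30589 genes, not normalized. Each of the 30589 genes has a single interval in it whose length is the whole span of the gene, so that reads in introns count with those in exons and reads of genes that overlap or lie antisense cannot be told apart without strand. Counts of close paralogs, such as the keratins KRT6A, KRT6B and KRT6C, the globins and the MHC genes, may have exchanged reads and are uncertain as separate values. The second deposited table holds a normalized signal per gene and library, made by the authors with no method stated in its header. Each of its values equals the raw count divided by 1 factor per library, and factors recomputed by the median of ratios gave back the counts within a relative difference of 5e-07, with factors from 0.557 to 1.72. The counts were used for every test, and the normalized values only for this check. Genes carry the symbols of the count table, 24454 of whose 30589 identifiers matched a symbol in a table of RefSeq genes for the assembly ARS-UCD2.0. That table was used for names only, and chromosome positions are those of the count table, on ARS-UCD1.2. Identifiers starting with LOC number 10582.

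Libraries were grouped by phenotype and time from their labels. In the main test edgeR's quasi-likelihood method was fitted to all 4 groups at once (edgeR 4.0.16 in R 4.3.3), with TMM normalization and without a block for the animal. Genes were kept by edgeR's expression filter with a minimum count of 10, which left 15988. All tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within each comparison, and an adjusted p under 0.05 is called past. The 5 comparisons were after versus before in resistant animals, the same in susceptible animals, resistant versus susceptible before, the same after, and the response difference. Log2 fold changes are those of the edgeR fit with a standard error, folds are their antilog, and CPM are TMM-scaled counts per library. At 7893430 to 21132093 counts per library the median standard error of a log2 fold change was 0.116 in resistant animals after versus before.

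A set of 40 gene lists was fixed: basal keratinocyte, cornified barrier, activated keratinocyte, hair follicle, sebaceous gland lipid, sweat gland, melanocyte, fibroblast and matrix, endothelium, endothelial activation and adhesion, smooth muscle, skeletal muscle, adipocyte, neutrophil, monocyte and macrophage, dendritic cell, T cell, cytotoxic and NK cell, B and plasma cell, mast cell and basophil, eosinophil, inflammatory cytokine and chemokine, type 2 immunity, interferon response, antigen presentation, complement and acute phase, coagulation and fibrinolysis, matrix remodelling and wound repair, immediate early response, heat shock, cell cycle, glucocorticoid response, circadian clock, hypoxia and glycolysis, red blood cell, nerve and Schwann cell, lipoxygenase and prostaglandin, antimicrobial and defensin, ribosomal protein, and mitochondrial genome transcript. Some genes stand in more than 1 list. A library's list score is the mean log2 CPM (prior count 2) of the members that passed the filter, with at least 3 needed. Differences of group means were tested with 100000 random exchanges of libraries between both groups, or, for the response difference, of phenotypes between animals, and adjusted over the 40 lists. The same lists were tested with camera in limma 3.58.1 with the correlation between genes estimated from the data.

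The comparisons, the tests, the lists, the rule for named genes and all alternatives except those said to be added were chosen before the data were examined. The rule names, per comparison and among genes with a symbol and an average log2 CPM of at least 0, the 8 rising and 8 falling genes of largest fold change past the threshold, or the 5 of smallest p where fewer than 3 genes pass. It adds up to 4 members of smallest p from each list described. Some genes that this rule selects are not reported here. Lists from which members were named in the comparisons of time were those past in any comparison or with at least 3 members called, and some of these members are given with the observations or not at all. Elsewhere they were those with a member called over the list alone or an unadjusted p under 0.05. That definition was set after the data had been seen. After infestation 3 genes passed between the phenotypes, of which 2 have a symbol. Members named because they were called against the direction of their list, or as its only called member, and standing outside the rule (EREG, TNF, CCL20, CXCL3, IL25, LYZ2 and NFIL3, IL1A in resistant animals, and CXCL9 and PDK1 in susceptible animals) were chosen after their values were seen.

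Before and after libraries of an animal share its tag in the labels, so that they come from the same animal. Deviations from the group means correlated with a median of 0.39 between libraries of the same animal, above 0.1 in 37 of 39 animals, and with -0.0111 between different animals. By 100 genes chosen without reference to the animal, 39 of 39 animals matched best with their own second library, and by all genes 29 did. Fits with the animal as a block were therefore alternatives for the comparisons of time.

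The other alternatives were DESeq2's size factors in edgeR, no filter on low counts, a filter of at least 1 CPM in 19 libraries, the DESeq2 Wald test (1.42.0), limma voom, limma voom with sample quality weights, 2 surrogate variables from sva 3.50.0, a fit to the compared groups only, a block on the animal number that the phenotypes share, and limma voom with the animal as a random block. For the lists they were DESeq2's size factors, the median of members, signs of the change exchanged within animals, and camera. Fits without each library in turn and without the library of lowest median correlation within each group were added after the data had been seen. Other splits of the samples exchanged before and after within animals, or phenotypes between animals, in 100 splits each with the real one included. Lists were computed and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

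The gene test was tried on simulated counts, drawn from the means, spreads and sizes of the real libraries with 200 genes changed. Each library was drawn independently, without an effect of the animal, so that shares recovered and false calls hold for such data only. For resistant after versus before, 70.1% of genes changed 1.5-fold, 89.6% of those changed 2-fold and 98.5% of those changed 4-fold were recovered among 15987 genes, with 8 false calls. The shares were 62.7%, 91% and 100% for susceptible after versus before (15987 genes, 11 false calls), and 73.1%, 88.1% and 100% for resistant versus susceptible before (15986 genes, 10 false calls). They were 68.7%, 88.1% and 98.5% for resistant versus susceptible after (15987 genes, 10 false calls), and 41.8%, 80.6% and 97% for the response difference (15987 genes, 11 false calls). The list test was tried on independent normal scores, not drawn from the real libraries, with no pairing and no correlation between lists. Of 10 lists shifted by 1 SD in these, 9 were recovered for resistant after versus before and 7 for resistant versus susceptible after, with 0 false calls among 40. Pieces left out are the hour of day of the biopsies, which the sources used here do not give, and any skin biopsied again without larvae, which was not analysed here.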

Results

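Skin biopsies were collected from 39 Braford cattle, a breed derived from Brahman and Hereford animals, before and 24 h after each animal was infested with about 20000 larvae of the cattle tick Rhipicephalus microplus. The labels class 20 animals as resistant and 19 as susceptible to ticks. RNA sequencing gave 1 library per biopsy and 78 libraries in 4 groups. These were 20 from resistant animals before, 20 from resistant animals after, 19 from susceptible animals before and 19 from susceptible animals after infestation. Total counts per library ranged from 10199878 to 17219827 in resistant animals before and from 8787994 to 17828301 after infestation. They ranged from 7893430 to 18981592 in susceptible animals before and from 8714180 to 21132093 after it. Between 18464 and 20352 genes were detected per library. Of 30589 genes in the count table, 15988 passed the expression filter and were tested. The first principal component held 15.1% of the variance and the second 11.9%. On the first, susceptible before replicate 2 stood apart at 120, against at most 71.3 in the other libraries. Its median correlation with its group was 0.852, its 10 most abundant genes took 22.6% of its counts, and the epidermal keratin KRT6A lay at 69.5 CPM in it, against at least 519 CPM in the other libraries from before infestation. On the second component, libraries from before infestation averaged 16.2 ± 10.6 (SD, n = 20) in resistant and 15.3 ± 10.4 (SD, n = 19) in susceptible animals. After it they averaged -14.5 ± 17.3 (SD, n = 20) and -17.1 ± 23.0 (SD, n = 19). The 10 most abundant genes took 12.5% ± 2.09 (SD, n = 20) of the counts before and 10.4% ± 1.51 (SD, n = 20) after infestation in resistant animals. In susceptible animals they took 13.3% ± 2.99 and 11.1% ± 2.84 (SD, n = 19). Every library from after infestation is also the second biopsy of its animal, and biopsies repeated without larvae were not analysed here.

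The first comparison asked which genes changed in the skin of resistant animals within 24 h of infestation. MMP1, the interstitial collagenase that cleaves fibrillar collagen (chromosome 15, 5811627 to 5820952, ARS-UCD1.2), rose 17.3-fold, from 4.71 ± 4.22 to 81.6 ± 70.2 CPM (SD, n = 20), and was higher after infestation in 19 of 20 animals. TNC, the extracellular matrix glycoprotein tenascin C of healing wounds, rose 5.74-fold and was higher in 20 of 20 animals. IL24, a cytokine of the IL-10 family (chromosome 16, 4682082 to 4687617), had the largest rise among the named genes, 28.9-fold from 0.108 ± 0.0919 to 3.33 ± 3.62 CPM. The adult beta globin gene HBB (chromosome 15, 48362354 to 48363996) fell 20.5-fold, from 22.2 ± 44.2 to 1.08 ± 1.46 CPM, and 11.9-fold without resistant before replicate 3. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2312 of 15988 genes passed an adjusted p of 0.05, 1213 higher and 1099 lower. Of these, 139 of the higher and 135 of the lower genes changed at least 2-fold. The other genes with the largest rises were PF4, a platelet and monocyte chemokine (log2 fold change 3.75 ± 0.48 SE), and FGF23, a hormone of phosphate balance (3.64 ± 0.50). They were followed by the anion exchanger SLC26A4 (3.54 ± 0.57), the neutrophil chemoattractant CXCL8 (3.53 ± 0.61), IL20 (3.27 ± 0.52) and oncostatin M, OSM (3.04 ± 0.46). SLC26A4, IL20 and OSM started near the floor, at 0.142, 0.303 and 0.218 CPM, and were higher in 19, 18 and 19 of 20 animals. The other largest falls were in CYP1A1, a xenobiotic-metabolising enzyme (-3.94 ± 0.63, and -4.58 without resistant after replicate 17), the B cell chemoattractant CXCL13 (-2.71 ± 0.42) and the nucleoside transporter SLC28A2 (-2.60 ± 0.35). BPIFA2C (-2.59 ± 0.45), ISG15 (-2.28 ± 0.47), LACTBL1 (-1.96 ± 0.38) and MX2 (-1.94 ± 0.49) were also called lower. Of these, ISG15 was nonetheless higher after infestation in 10 of 20 animals and MX2 in 12 of 20. With the animal as a block 3502 genes passed, and with 2 surrogate variables 4245 did. Of the genes named here, ISG15 and MX2 did not pass with the animal as a block (-0.61, adjusted p = 0.236, and -0.08, adjusted p = 0.913, by edgeR). Nor did they by limma voom (-0.70, adjusted p = 0.263, and -0.17, adjusted p = 0.836). Without resistant before replicate 20 the log2 fold changes by edgeR were -1.45 for ISG15 and -0.85 for MX2, which did not pass (adjusted p = 0.17).

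Of the 40 gene lists fixed before the data were examined, 22 shifted in resistant animals by a permutation test of the mean log2 CPM of their members, 15 higher and 7 lower. The matrix remodelling and wound repair list rose by 0.79 ± 0.12 (SE, n = 20 and 20, adjusted p = 0.0002, adjusted p = 0.258 with an estimated correlation), resting on a raw p of 1e-05, the smallest that 100000 resamples can give. In it 9 of 20 measured members rose, 1 (EREG) fell and 10 did not pass (adjusted over the list alone, 11 rose and 1 fell). They included MMP1, TNC, the macrophage elastase MMP12 (2.25 ± 0.41) and PDPN (0.91 ± 0.16). The inflammatory cytokine and chemokine list rose by 0.78 ± 0.20 (adjusted p = 0.00156, adjusted p = 0.365 with an estimated correlation). In it 7 of 21 members were higher, 3 lower and 11 not past (adjusted over the list alone, 10 and 5). Next to IL24, IL20 and OSM, the neutrophil chemoattractant CXCL5 rose (2.52 ± 0.37), whereas IL1A, TNF and CCL20 fell. CCL20 did not pass in 15 of the 40 fits that left out 1 library, with log2 fold changes from -1.25 to -1.0 over the 40. In the activated keratinocyte list (0.53 ± 0.16, adjusted p = 0.0057, adjusted p = 0.376 with an estimated correlation), 5 of 16 members rose, 1 fell and 10 did not pass (adjusted over the list alone, 6 and 1). The keratins of injured epidermis KRT6A (3.88-fold, 748 ± 119 to 2900 ± 1500 CPM), KRT6C (4.10-fold) and KRT6B (7.44-fold) and KRT17 (1.68-fold) rose, and the member that fell was S100A7 (-0.88 ± 0.22). KRT6A, KRT6B and KRT6C are close paralogs whose reads the counting could have exchanged, so that their separate values are uncertain. By camera with an estimated correlation, which tests members against all other genes and not against 0 shift, none of the 22 lists passed.

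Of the immune cell lists in resistant animals, those of mast cells, eosinophils, neutrophils and dendritic cells rose by permutation, and those of monocytes, T cells, cytotoxic cells and B and plasma cells (-0.32 ± 0.17 SE, adjusted p = 0.101 by permutation) did not pass. In the mast cell and basophil list (0.50 ± 0.13 SE, permutation adjusted p = 0.00156, adjusted p = 0.284 with an estimated correlation), 5 of 11 measured members rose and none fell (adjusted over the list alone, 6 and 0). The examples are the high-affinity IgE receptor chain FCER1A (3.19-fold, 5.63 ± 2.18 to 18.0 ± 9.08 CPM, SD, n = 20), the histamine-forming enzyme HDC (2.08-fold) and the mast cell protease CPA3 (1.74-fold). Of the 10 members of the eosinophil list only 3 passed the expression filter, and its mean score was low, -0.39 log2 CPM before and 0.48 after infestation. In this list (0.86 ± 0.21, adjusted p = 0.0012, adjusted p = 0.258 with an estimated correlation), 2 of the 3 measured members rose (adjusted over the list alone, 3). These were the lipoxygenase ALOX15 (3.03-fold) and the interleukin-5 receptor IL5RA (2.81-fold, 0.484 ± 0.477 to 1.44 ± 1.5 CPM). By limma voom neither passed (0.91, adjusted p = 0.0522, and 1.24, adjusted p = 0.0601). The neutrophil list rose by 0.62 ± 0.14 (adjusted p = 0.0012, adjusted p = 0.258 with an estimated correlation). In it 5 of 13 members were higher (adjusted over the list alone, 8). They included PADI4 (1.6-fold), MMP25 (1.79-fold) and PGLYRP1 (5.96-fold, and 3.64-fold without resistant after replicate 3). In the dendritic cell list (0.44 ± 0.12, adjusted p = 0.00156, adjusted p = 0.284 with an estimated correlation), 4 of 12 members rose (adjusted over the list alone, 5). Among them were the transcription factor BATF3 (3.36-fold), the lymph node homing receptor CCR7 (2.51-fold) and FSCN1 (1.38-fold). The monocyte and macrophage list did not pass (0.27 ± 0.18, adjusted p = 0.174), although 4 of its 12 members rose (adjusted over the list alone, 5 rose and 3 fell), including the mannose receptor MRC1 (2.63-fold) and ITGAM (1.95-fold). None of the 18 members of the T cell list passed by edgeR (0.28 ± 0.14, adjusted p = 0.0806, and 0 adjusted over the list alone). With the animal as a block 3 rose, CD4 (0.76, adjusted p = 0.00838), LCK (0.25, adjusted p = 0.022) and CD2 (0.44, adjusted p = 0.0309), and limma voom called CD4 (0.77, adjusted p = 0.0448). In the cytotoxic and NK cell list (0.16 ± 0.14, adjusted p = 0.332) 1 of 11 did, GZMB, and 0 adjusted over the list alone. GZMB did not pass in 12 of the 40 fits that left out 1 library, with log2 fold changes from 0.61 to 0.92 over the 40. With the median of members as the score the monocyte list (0.61, adjusted p = 0.0115, adjusted p = 0.564 with an estimated correlation) and the T cell list (0.36, adjusted p = 0.0376, adjusted p = 0.501 with an estimated correlation) passed by permutation.

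Further lists rose in resistant animals. In the antimicrobial and defensin list (0.58 ± 0.14 SE, permutation adjusted p = 0.0012, adjusted p = 0.258 with an estimated correlation, n = 20 and 20), 7 of 13 measured members rose, S100A7 and LYZ2 fell and 4 did not pass (adjusted over the list alone, 8 and 3). The beta-defensin DEFB13 rose 2.83-fold. LYZ2 did not pass with the animal as a block (-0.97, adjusted p = 0.0662 by edgeR) or without resistant before replicate 11 (-0.88). The complement and acute phase list rose by 0.47 ± 0.13 (adjusted p = 0.00264, adjusted p = 0.303 with an estimated correlation). In it 7 of 18 members were higher (adjusted over the list alone, 8). Examples are complement factor B, CFB (2.22-fold), ceruloplasmin, CP (1.44-fold), and C3 (1.63-fold). In the hair follicle list (0.37 ± 0.11, adjusted p = 0.0057, adjusted p = 0.376 with an estimated correlation), 10 of 28 members rose (adjusted over the list alone, 16). These included the inner root sheath genes PADI3 (1.69-fold), KRT74 (1.83-fold) and KRT71 (1.76-fold). The coagulation and fibrinolysis list rose by 0.26 ± 0.07 (adjusted p = 0.00406, adjusted p = 0.284 with an estimated correlation). In it 6 of 17 members were higher (adjusted over the list alone, 6), including urokinase, PLAU (1.76-fold), and thrombomodulin, THBD (1.73-fold). In the heat shock list (0.24 ± 0.07, adjusted p = 0.00307, adjusted p = 0.284 with an estimated correlation), 6 of 13 members rose (adjusted over the list alone, 8), led by HSPH1 (1.38-fold) and CHORDC1 (1.31-fold). Without resistant after replicate 6 only 2 were called. The type 2 immunity list rose by 0.17 ± 0.07 (adjusted p = 0.0267, adjusted p = 0.356 with an estimated correlation). In it 4 of 14 members were higher, IL25 and CCL24 lower and 8 not past (adjusted over the list alone, 6 and 3). In it the T helper 2 cell chemokine CCL22 rose 3.74-fold and the receptor OSMR 1.70-fold. CCL24 did not pass in 19 of the 40 fits that left out 1 library, with log2 fold changes from -1.01 to -0.70 over the 40. In the hypoxia and glycolysis list (0.16 ± 0.05, adjusted p = 0.0106, adjusted p = 0.376 with an estimated correlation), 5 of 16 members rose and PDK1 fell (adjusted over the list alone, 5 and 2), led by NDRG1 (1.71-fold) and enolase, ENO1 (1.38-fold). In the basal keratinocyte list (0.16 ± 0.07, adjusted p = 0.0475, adjusted p = 0.427 with an estimated correlation), KRT14 (1.52-fold) and TP63 (1.22-fold) rose, KRT15 fell and 7 of 10 did not pass (adjusted over the list alone, 3 and 1). KRT15 did not pass without resistant before replicate 9 or resistant after replicate 3 or 15, with log2 fold changes no weaker than -0.33. The call on the basal keratinocyte list was lost with DESeq2's size factors (adjusted p = 0.056). With the median of members as the score the complement (adjusted p = 0.107), hypoxia (0.657), type 2 immunity (0.938) and basal keratinocyte (0.938) lists did not pass by permutation.

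Lower after infestation in resistant animals were markers of smooth muscle, nerve and melanocytes, and genes of the circadian clock. In the smooth muscle list (-0.39 ± 0.11 SE, permutation adjusted p = 0.00307, adjusted p = 0.284 with an estimated correlation, n = 20 and 20), 6 of 10 measured members fell (adjusted over the list alone, 8). They included the contractile proteins ACTG2 (log2 fold change -0.77 ± 0.16), CNN1 (-0.65 ± 0.14) and MYLK (-0.42 ± 0.10). In the nerve and Schwann cell list (-0.34 ± 0.11, adjusted p = 0.0057, adjusted p = 0.258 with an estimated correlation), 6 of 12 members fell (adjusted over the list alone, 6), led by the myelin gene MBP (-0.59 ± 0.10) and SOX10 (-0.48 ± 0.13). Without resistant before replicate 5 only 3 were called. In the melanocyte list (-0.33 ± 0.14, adjusted p = 0.0475, adjusted p = 0.284 with an estimated correlation), 3 of 12 members fell (adjusted over the list alone, 5), led by the melanosome transporter SLC45A2 (-0.70 ± 0.15) and SOX10, which also stands in the nerve list. With the animal as a block 7 fell. The circadian clock list fell by 0.34 ± 0.07 (adjusted p = 0.0004, adjusted p = 0.258 with an estimated correlation). In it 8 of 17 members were lower, NFIL3 higher and 8 not past (adjusted over the list alone, 9 lower and 1 higher). Its clearest falls were in the clock repressor PER2 (-0.79 ± 0.14) and the clock output factor HLF (-0.58 ± 0.10), each lower in 18 of 20 animals. The red blood cell list fell by 1.04 ± 0.19 (adjusted p = 0.0002, adjusted p = 0.501 with an estimated correlation), through HBB alone of its 3 measured members (adjusted over the list alone, 1), and the median log2 fold change of its members was 0.01. The mitochondrial genome transcript list fell by 0.19 ± 0.07 (adjusted p = 0.0243, adjusted p = 0.365 with an estimated correlation), with 0 of 13 members past by edgeR (adjusted over the list alone, 5 lower). With the animal as a block 6 fell, among them ND4 (-0.22, adjusted p = 0.0337), COX3 (-0.20, adjusted p = 0.0345), ND3 (-0.27, adjusted p = 0.0389) and ND6 (-0.23, adjusted p = 0.0435). In the skeletal muscle list (-0.18 ± 0.07, adjusted p = 0.0405, adjusted p = 0.699 with an estimated correlation) ACTN2 fell, the slow myosin MYH7 rose 1.87-fold and 8 of 10 members did not pass (adjusted over the list alone, 1 and 1). The skeletal muscle list did not pass within animals (adjusted p = 0.0517). With the median of members as the score its shift was 0.01, and neither it (adjusted p = 0.938) nor the nerve (0.088), melanocyte (0.137), clock (0.103) or mitochondrial (0.208) list passed by permutation.

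The interferon response list did not pass as a list in resistant animals (-0.40 ± 0.25 SE, permutation adjusted p = 0.168, n = 20 and 20), although 18 of 26 measured members were called lower and none higher by edgeR (adjusted over the list alone, 20). The antiviral gene RSAD2 went from 28.4 ± 52.7 to 7.65 ± 2.44 CPM (SD, n = 20), CMPK2 from 34.7 ± 38.9 to 15.4 ± 3.15 CPM and ISG15 from 53.6 ± 114 to 11.0 ± 5.13 CPM. Without resistant before replicate 20 RSAD2 fell 2.29-fold. Only 3 members were called with the animal as a block, 3 by limma voom, and 5 by edgeR without resistant before replicate 20, whose list score was 7.2 against 5.83 in the next highest library of its group. In the fibroblast and matrix list (-0.24 ± 0.14, adjusted p = 0.15), 5 of 18 members fell and the growth factor receptor PDGFRA rose (1.54-fold) (adjusted over the list alone, 5 and 1). The fallen members were led by the type I collagen genes COL1A2, from 12400 ± 6680 to 5610 ± 2560 CPM, and COL1A1, from 16200 ± 9630 to 7400 ± 3340 CPM. In the sweat gland list (-0.15 ± 0.09, adjusted p = 0.144), the water channel AQP5 fell (-1.63 ± 0.36) and carbonic anhydrase 2, CA2, rose (1.78-fold). In it 3 of 12 members were higher and 2 lower (adjusted over the list alone, 3 and 2), and without resistant after replicate 11 only 3 were called in all. In the glucocorticoid response list (-0.17 ± 0.09, adjusted p = 0.103), 6 of 15 members fell and 2 rose (adjusted over the list alone, 6 and 2), and TSC22D3 fell in 20 of 20 animals. In the adipocyte list (-0.34 ± 0.45, adjusted p = 0.515), FABP4 (-0.82 ± 0.27), LPL (-1.19 ± 0.41) and CIDEC (-1.92 ± 0.69) of 8 members fell (adjusted over the list alone, 3). Without resistant before replicate 5 none of these passed, LPL lying at -0.56 and CIDEC at -0.88, and with the animal as a block LPL (-0.51, adjusted p = 0.277 by edgeR) and CIDEC (-0.62, adjusted p = 0.557) did not pass. CIDEC did not pass in 22 of the 40 fits that left out 1 library, but lay at -2.73 without resistant after replicate 13 (adjusted p = 0.00426 by edgeR). By limma voom none of FABP4, LPL and CIDEC was called. The other 10 lists not past were cornified barrier, sebaceous gland lipid, endothelium, endothelial activation and adhesion, B and plasma cell, antigen presentation, immediate early response, cell cycle, lipoxygenase and prostaglandin, and ribosomal protein, whose shifts lay between -0.32 (B and plasma cell) and 0.11. Of these the cornified barrier list had 1 member higher and 3 lower, sebaceous gland 4 and 3, and immediate early response 0 and 5 (adjusted over the list alone, 1 and 4, 4 and 6, and 0 and 5). Scored by the median of members, the cornified barrier list passed by permutation (-0.32, adjusted p = 0.0155), but by its mean score (-0.20 ± 0.11, adjusted p = 0.128) and with an estimated correlation (adjusted p = 0.696) it did not.

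**Figure D1:**
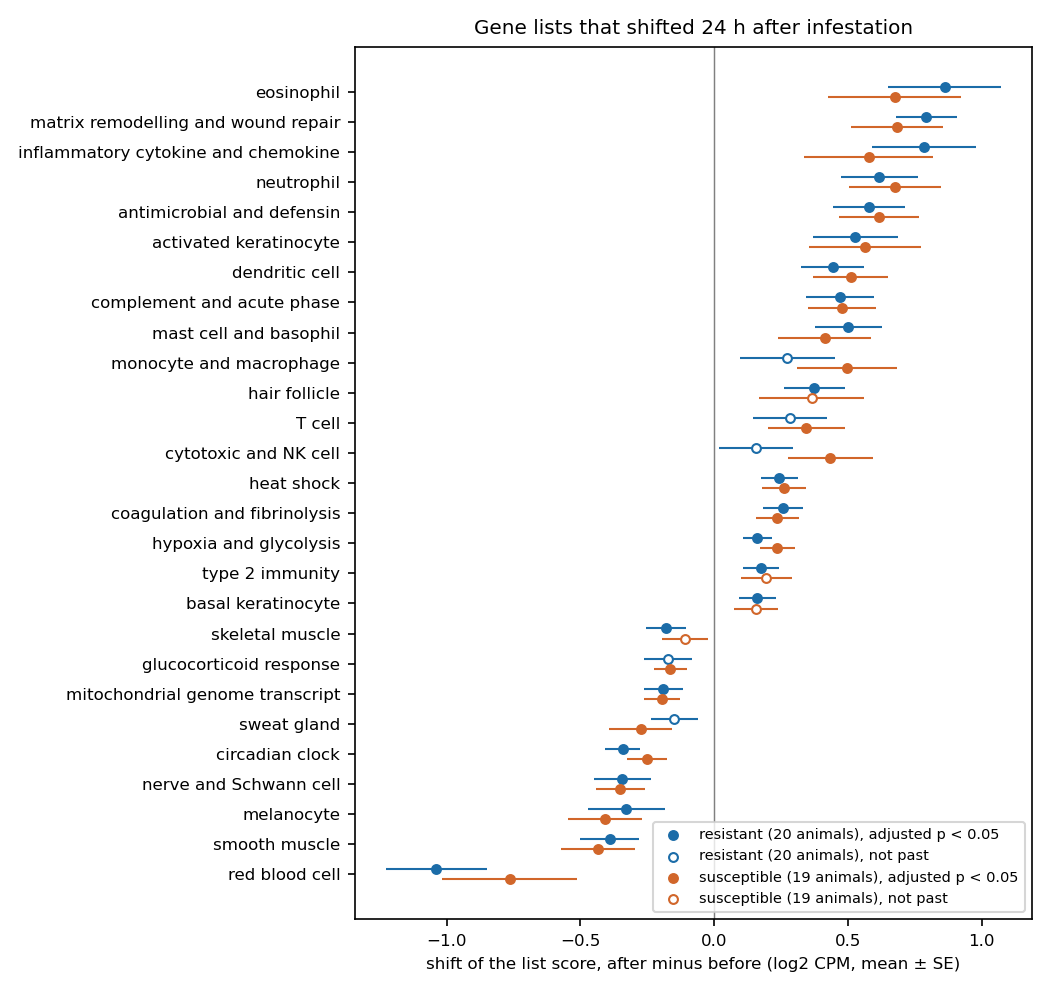
Shift of each list score from before to after infestation (mean difference in log2 CPM, bars ± SE) for resistant (20 animals) and susceptible (19 animals) cattle, for lists past an adjusted p of 0.05 in at least 1 phenotype. Filled points mark lists past the threshold by a permutation test and open points those not past; matrix remodelling rose by 0.79 and 0.68, and smooth muscle lay at -0.39 and -0.43.

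The same comparison in susceptible animals gave 2188 of 15988 genes past an adjusted p of 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1089 higher and 1099 lower, of which 148 and 115 changed at least 2-fold. FGF23 rose most among the named genes, 23.4-fold from 0.506 ± 0.716 to 13.4 ± 20.3 CPM (SD, n = 19), and was higher in 18 of 19 animals. MMP1 rose 12.9-fold, from 3.87 ± 2.33 to 51 ± 67.7 CPM, TNC 4.46-fold and IL24 17.8-fold (9.66-fold without susceptible after replicate 6). The other largest rises were in the cytidine deaminase APOBEC3Z1 (log2 fold change 4.19 ± 0.68 SE), SLC26A4 (3.97 ± 0.65), PF4 (3.44 ± 0.49), CXCL8 (3.34 ± 0.60) and KRT6B (2.86 ± 0.43). APOBEC3Z1 (0.1 ± 0.124 to 2.15 ± 3.31 CPM) and SLC26A4 (0.082 ± 0.0733 to 1.49 ± 2.2 CPM) started near the floor. They were higher after infestation in 14 and 12 of 19 animals. PF4 rose 7.12-fold without susceptible after replicate 6 and 17.1-fold without susceptible before replicate 15. CXCL8 rose 5.97-fold without susceptible after replicate 14 and 24.5-fold without susceptible before replicate 14. HBB fell (-4.30 ± 0.77, and -3.42 without susceptible before replicate 15), followed by SLC28A2 (-3.19 ± 0.36), BPIFA2C (-2.25 ± 0.46) and the asialoglycoprotein receptor ASGR1 (-2.09 ± 0.29). LACTBL1 (-2.09 ± 0.40), CXCL13 (-2.07 ± 0.42), the milk casein CSN2 (-1.92 ± 0.60) and PHGR1 (-1.89 ± 0.38) fell next. CSN2 did not pass without susceptible before replicate 6 (-0.71, adjusted p = 0.426 by edgeR). By limma voom HBB (-2.56, adjusted p = 0.0809), IL24 (1.92, adjusted p = 0.0979) and CSN2 (-0.63, adjusted p = 0.593) did not pass, and with sample quality weights neither did APOBEC3Z1 (1.97, adjusted p = 0.0542). With 2 surrogate variables 3655 genes passed, and 1455 did in a fit to these 2 groups alone.

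Of the 40 lists, 23 shifted in susceptible animals by the permutation test, 15 higher and 8 lower. The matrix remodelling and wound repair list rose by 0.68 ± 0.17 (SE, n = 19 and 19, adjusted p = 0.004, adjusted p = 0.216 with an estimated correlation). In it 10 of 20 measured members were higher (adjusted over the list alone, 11 higher and 1 lower), including MMP12 (7.14-fold, and 4.61-fold without susceptible after replicate 6). In the activated keratinocyte list (0.56 ± 0.21, adjusted p = 0.0219, adjusted p = 0.305 with an estimated correlation), 6 of 16 members rose and S100A7 fell (adjusted over the list alone, 7 and 2), with KRT6A at 3.57-fold. The inflammatory cytokine and chemokine list rose by 0.58 ± 0.24 (adjusted p = 0.0389, adjusted p = 0.408 with an estimated correlation). In it 6 of 21 members were higher and IL1A, CXCL3 and CCL20 lower (adjusted over the list alone, 7 and 3). With the animal as a block CXCL3 (-0.39, adjusted p = 0.35) and CCL20 (-0.14, adjusted p = 0.812) did not pass by edgeR. Neither passed without susceptible before replicate 14, nor CCL20 without susceptible before replicate 11, and the weakest log2 fold changes were -0.18 for CXCL3 and -0.45 for CCL20. In the antimicrobial and defensin list (0.62 ± 0.15, adjusted p = 0.004, adjusted p = 0.216 with an estimated correlation), 5 of 13 members rose and S100A7 fell (adjusted over the list alone, 8 and 1), with DEFB13 at 5.65-fold and PGLYRP1 at 5.83-fold. The complement list rose by 0.48 ± 0.13 (adjusted p = 0.00463, adjusted p = 0.274 with an estimated correlation). In it 7 of 18 members were higher (adjusted over the list alone, 9), led by CFB (2.07-fold) and C2 (1.68-fold). In the coagulation list (0.24 ± 0.08, adjusted p = 0.0136, adjusted p = 0.305 with an estimated correlation), 5 of 17 members rose (adjusted over the list alone, 6 higher and 1 lower), led by PLAU (1.88-fold). Without susceptible after replicate 6 only 4 complement members and 3 coagulation members were called. The hypoxia and glycolysis list rose by 0.24 ± 0.06 (adjusted p = 0.00456, adjusted p = 0.216 with an estimated correlation). In it 6 of 16 members were higher and PDK1 lower (adjusted over the list alone, 7 and 1), led by NDRG1 (2.11-fold). In the heat shock list (0.26 ± 0.08, adjusted p = 0.0111, adjusted p = 0.228 with an estimated correlation), 5 of 13 members rose (adjusted over the list alone, 7), led by BAG3 (1.33-fold) and HSPH1 (1.39-fold). Without susceptible before replicate 7, 2 were called. By camera with an estimated correlation, against all other genes, none of the 23 lists passed. With the median of members as the score the cytokine (adjusted p = 0.099), complement (0.104), hypoxia (0.311) and heat shock (0.0593) lists did not pass by permutation.

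In susceptible animals 7 immune cell lists rose by permutation, and the B and plasma cell list did not pass. In the neutrophil list (0.68 ± 0.17 SE, permutation adjusted p = 0.00413, adjusted p = 0.216 with an estimated correlation, n = 19 and 19), 6 of 13 measured members rose (adjusted over the list alone, 7), led by MMP9 (2.36-fold). In the monocyte and macrophage list (0.50 ± 0.19, adjusted p = 0.0219, adjusted p = 0.305 with an estimated correlation), 6 of 12 members rose (adjusted over the list alone, 8), led by ITGAM (2.23-fold), MRC1 (2.14-fold) and the endotoxin co-receptor CD14 (1.55-fold). The dendritic cell list rose by 0.51 ± 0.14 (adjusted p = 0.00463, adjusted p = 0.216 with an estimated correlation). In it 5 of 12 members were higher (adjusted over the list alone, 7), led by BATF3 (3.71-fold) and FSCN1 (1.62-fold). Without susceptible after replicate 6, 3 were called. In the T cell list (0.35 ± 0.14, adjusted p = 0.0389, adjusted p = 0.374 with an estimated correlation), 4 of 18 members rose (adjusted over the list alone, 4), led by CD8B (2.00-fold) and CD2 (1.51-fold). The cytotoxic and NK cell list rose by 0.43 ± 0.16 (adjusted p = 0.0219, adjusted p = 0.305 with an estimated correlation). In it 4 of 11 members were higher (adjusted over the list alone, 6), led by the chemokine CCL5 (1.70-fold). Without susceptible after replicate 5, 1 was called. In the mast cell and basophil list (0.41 ± 0.17, adjusted p = 0.0219, adjusted p = 0.374 with an estimated correlation), FCER1A (2.49-fold) and CPA3 (1.58-fold) rose among 11 members (adjusted over the list alone, 2). HDC lay at 0.51 ± 0.23 (adjusted p = 0.133 by edgeR) and passed with the animal as a block (0.59, adjusted p = 0.0188), under which 4 members were called. CPA3 did not pass without susceptible before replicate 8 or 15, or susceptible after replicate 5, 6, 15 or 19, with log2 fold changes from 0.58 to 0.73. In the eosinophil list (0.68 ± 0.25, adjusted p = 0.0219, adjusted p = 0.305 with an estimated correlation), IL5RA (2.99-fold) and ALOX15 (1.99-fold) rose among the 3 of 10 members that were measured (adjusted over the list alone, 2). ALOX15 did not pass with the animal as a block (0.89, adjusted p = 0.0541 by edgeR), nor in 19 of the 38 fits that left out 1 library, and its log2 fold change in those 38 fits ranged from 0.75 to 1.26. IL5RA did not pass by limma voom (1.04, adjusted p = 0.148). Scored by the median of members, the cytotoxic (adjusted p = 0.104) and mast cell (0.0767) lists did not pass by permutation.

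In susceptible animals the smooth muscle list fell (-0.43 ± 0.14 SE, permutation adjusted p = 0.0136, adjusted p = 0.228 with an estimated correlation, n = 19 and 19). In it 6 of 10 measured members were lower (adjusted over the list alone, 7), with CNN1 at -0.77 ± 0.14. So did the melanocyte list (-0.41 ± 0.14, adjusted p = 0.0149, adjusted p = 0.216 with an estimated correlation), with 6 of 12 lower (adjusted over the list alone, 6) and tyrosinase, TYR, at -0.68 ± 0.16. In the nerve and Schwann cell list (-0.35 ± 0.09, adjusted p = 0.00456, adjusted p = 0.216 with an estimated correlation), 4 of 12 members fell (adjusted over the list alone, 5). The circadian clock list fell by 0.25 ± 0.07 (adjusted p = 0.00605, adjusted p = 0.216 with an estimated correlation). In it 6 of 17 members were lower and NFIL3 higher (adjusted over the list alone, 9 and 1), led by HLF (-0.45 ± 0.10) and ARNTL (-0.35 ± 0.10). NFIL3 did not pass in 15 of the 38 fits that left out 1 library, with log2 fold changes from 0.23 to 0.33 over the 38. In the sweat gland list (-0.28 ± 0.12, adjusted p = 0.0389, adjusted p = 0.699 with an estimated correlation), 3 of 12 members fell and 2 rose (adjusted over the list alone, 3 and 2), with AQP5 at -1.73 ± 0.37 and CA2 at 0.66 ± 0.14. The glucocorticoid response list fell by 0.16 ± 0.06 (adjusted p = 0.0219, adjusted p = 0.374 with an estimated correlation). In it 6 of 15 members were lower and ANGPTL4 higher (adjusted over the list alone, 7 and 1), led by KLF15 (-0.57 ± 0.11). Without susceptible before replicate 14, 4 were called. The red blood cell list fell by 0.76 ± 0.25 (adjusted p = 0.0136, adjusted p = 0.305 with an estimated correlation), again through HBB alone of 3 members (adjusted over the list alone, 1). In the mitochondrial genome transcript list (-0.20 ± 0.07, adjusted p = 0.0167, adjusted p = 0.305 with an estimated correlation), 5 of 13 members fell (adjusted over the list alone, 5), led by ND2 (-0.44 ± 0.14) and ND3 (-0.34 ± 0.11). Without susceptible before replicate 2, 0 were called (ND2 -0.20, adjusted p = 0.192, and ND3 -0.28, adjusted p = 0.0677, by edgeR). ND2 also did not pass with the animal as a block (-0.29, adjusted p = 0.0575). Scored by the median of members, the melanocyte (adjusted p = 0.104), clock (0.363), sweat gland (0.363), glucocorticoid (0.218), red blood cell (0.287) and mitochondrial (0.0514) lists did not pass by permutation. The hair follicle list did not pass (0.37 ± 0.20, adjusted p = 0.0778), although 5 of 28 members rose (adjusted over the list alone, 8, and with the animal as a block, 8), with KRT71 at 1.75-fold. Nor did type 2 immunity (0.19 ± 0.10, adjusted p = 0.0778), with 4 of 14 higher (adjusted over the list alone, 4). In the interferon response list (0.03 ± 0.17, adjusted p = 0.957), 1 of 26 members, the T cell chemokine CXCL9, was called higher (adjusted over the list alone, 1). CXCL9 did not pass with the animal as a block (0.66, adjusted p = 0.204 by edgeR) or without susceptible after replicate 2 or 15 (lowest log2 fold change 1.07). In the fibroblast and matrix list (-0.03 ± 0.22, adjusted p = 0.957), 0 of 18 were called (adjusted over the list alone, 0). With the animal as a block 3 rose and 1 fell. The list was higher after infestation in 6 of 19 susceptible animals, as in 6 of 20 resistant animals. Its score went from 9.58 to 11.4 in susceptible replicate 5 and from 7.64 to 8.57 in susceptible replicate 2. The list was not tested without these animals, so that a fall in most animals stays open. In the basal keratinocyte list (0.16 ± 0.08, adjusted p = 0.103), KRT14 (1.58-fold), KRT5 (1.38-fold) and TP63 (0.26 ± 0.08) rose and KRT15 fell (adjusted over the list alone, 3 and 1). KRT15 did not pass without susceptible before replicate 10 or susceptible after replicate 6 or 19, with log2 fold changes no weaker than -0.35. The other 12 lists did not pass, with shifts between -0.55 (adipocyte) and 0.17. Of these the sebaceous gland list had 2 members higher and 3 lower and the immediate early list 0 and 3 (adjusted over the list alone, 3 and 4, and 1 and 3). Scored by the median of members, the lipoxygenase and prostaglandin list passed by permutation (-0.21, adjusted p = 0.0177), but by its mean score (-0.00237 ± 0.09, adjusted p = 0.988) and with an estimated correlation (adjusted p = 0.86) it did not.

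**Figure D2:**
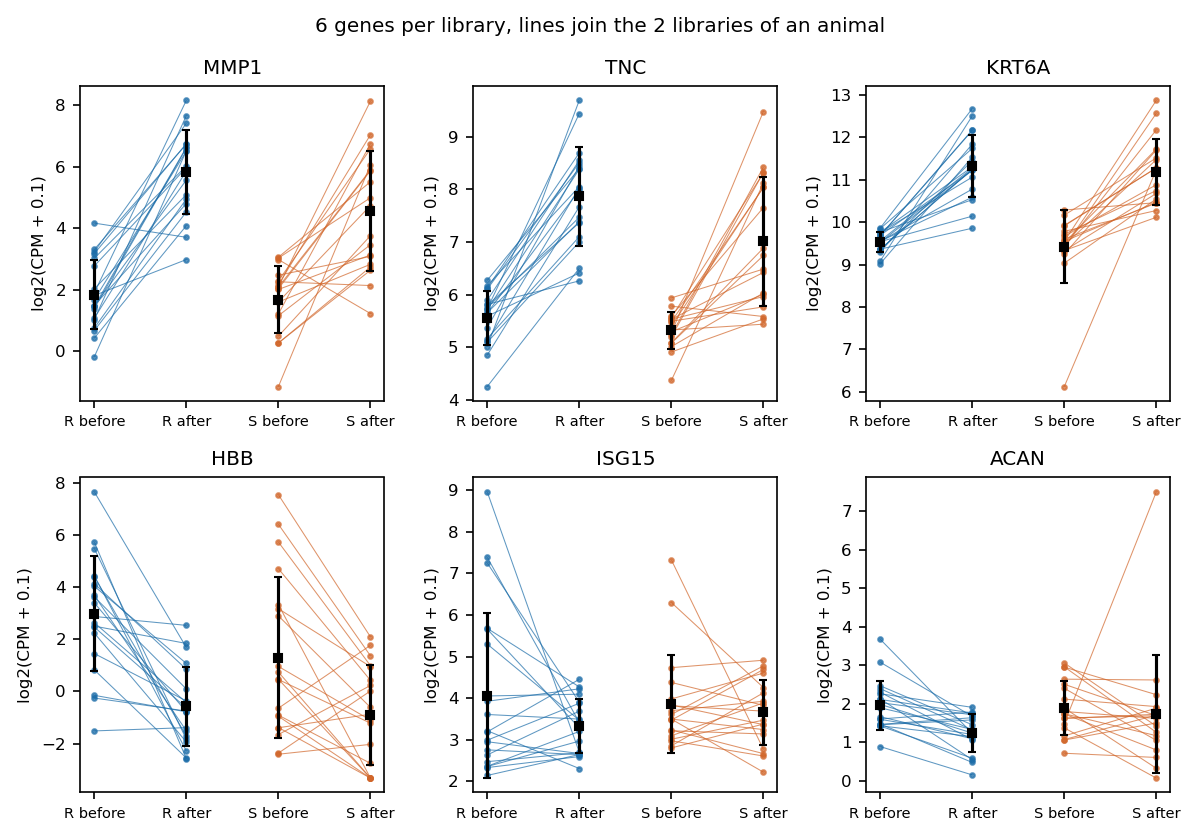
Expression of 6 genes in each library, as log2(CPM + 0.1), for resistant (R, 20 animals) and susceptible (S, 19 animals) cattle before and after infestation; lines join the libraries of 1 animal, squares are means and bars ± SD. MMP1, TNC and KRT6A were higher after infestation in at least 17 animals of each phenotype, while ISG15 was high in a few libraries from before infestation and ACAN in 1 susceptible library after it.

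The responses of both phenotypes were compared across genes. Of the 3245 genes called in either phenotype, 3190 had the same direction in both. In both phenotypes 660 genes were called higher, against 82.6 expected for independent lists of those sizes, 595 were called lower, against 75.5, and 0 were called in opposite directions. The log2 fold changes of the 15988 genes correlated with Pearson r = 0.801 and Spearman rho = 0.748. This correlation is across genes, which are not independent replicates, and the responses share no library. In mean log2 CPM differences r was 0.845, and 100 random exchanges of before and after within animals gave values from -0.681 to 0.611. Genes called in 1 phenotype only numbered 1057 in resistant and 933 in susceptible animals. None of these had a response difference past the threshold, but neither did any other of the 15988 genes, so that this is no separate check.

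**Figure D3:**
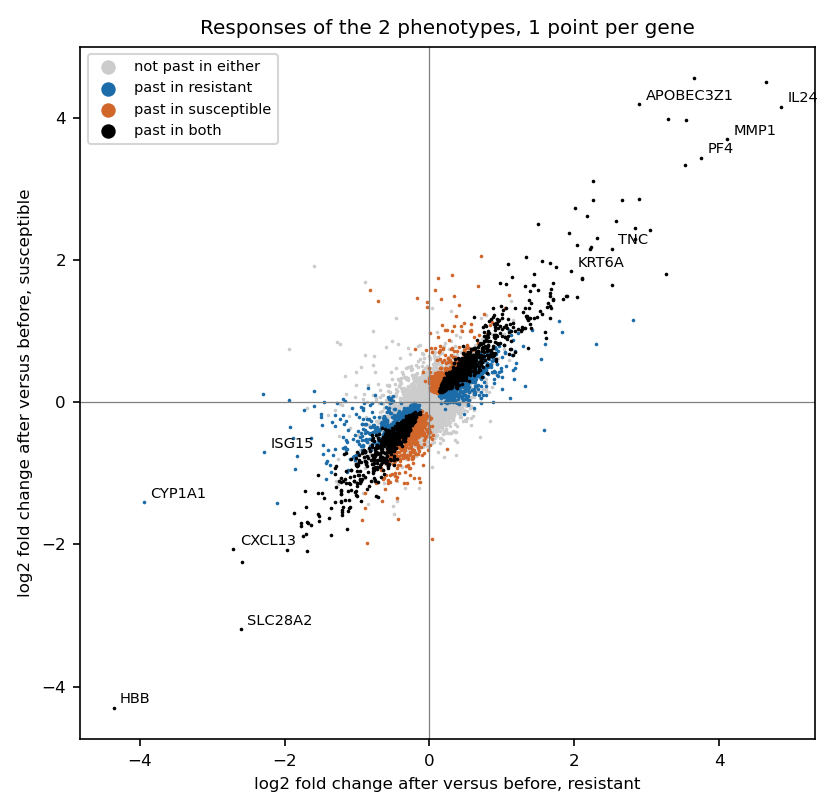
Log2 fold change after versus before infestation in resistant (horizontal axis) and susceptible (vertical axis) animals, 1 point per gene for 15988 genes, coloured by the phenotype in which the gene passed an adjusted p of 0.05. Points past the threshold in both phenotypes lie in the upper right (660 genes) and lower left (595 genes), and ISG15 and CYP1A1 passed in resistant animals only.

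Whether resistant and susceptible animals differed before any larvae were applied was tested next. No single gene passed, the lowest adjusted p being 0.602 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The count was 0 of 15988, with 1195 genes at an unadjusted p under 0.05. Other settings called 2 (DESeq2), 0 (limma voom), 0 (limma voom with quality weights) and 3 (edgeR without a low-count filter). The genes of smallest p, none of them past, were HHIPL2 (log2 fold change 1.36 ± 0.32 SE, resistant minus susceptible), WFDC2 (-1.34 ± 0.32), DHRS7 (-0.68 ± 0.17), METTL23 (-0.49 ± 0.12) and the non-classical MHC class I gene BOLA-NC1 (0.38 ± 0.10). BOLA-NC1 lay at 234 ± 54.9 CPM (SD, n = 20) in resistant and 179 ± 39.1 CPM (SD, n = 19) in susceptible animals. No list passed (40 tested, 0 at an unadjusted p under 0.05, lowest adjusted p = 0.881 by permutation). Adjusted over the list alone, 6 of 8 members of the adipocyte list were higher in resistant animals, led by the lipases LIPE (1.09 ± 0.32) and LPL (1.36 ± 0.42), against 0 over all genes. In the interferon response list 17 of 26 members were higher adjusted over the list alone and 0 over all genes, led by MX2 (1.80 ± 0.50) and ZNFX1 (0.61 ± 0.18). The list scores themselves differed by 0.26 ± 0.40 (adipocyte) and 0.29 ± 0.27 (interferon), both with adjusted p = 0.881. Without resistant before replicate 5, 0 adipocyte members were past over the list alone (LPL 0.73), and without resistant before replicate 20, 0 interferon members were (MX2 0.72). Adjusted over the list alone, BOLA-NC1 of 20 antigen presentation genes was also higher, and HP and LCN2 of 18 complement and acute phase genes were lower in resistant animals. In 7 of the 39 fits that left out 1 library, 0 complement genes were past over the list alone, and HP went from -1.52 to -0.23 without susceptible before replicate 16.

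After infestation 3 genes differed between the phenotypes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, all lower in resistant animals. There were 664 genes at an unadjusted p under 0.05. The called genes were ACAN, the cartilage proteoglycan aggrecan (chromosome 21, 20377694 to 20447099, -2.33 ± 0.44 SE, adjusted p = 0.00691), and the stromal protease MMP11 (chromosome 17, 71231342 to 71240517, -1.68 ± 0.33, adjusted p = 0.0134). The other was the unnamed locus LOC101906766 (-3.35 ± 0.62, adjusted p = 0.00691), which lies outside the rule for named genes and was chosen after its values were seen. Susceptible after replicate 5 held ACAN at 7.51 and MMP11 at 8.22 log2 CPM, against highest values of 3.69 and 3.49 in the other 77 libraries. Without it 0 genes passed, and the log2 fold changes were -0.23 for ACAN, -0.15 for MMP11 (both adjusted p = 0.922 by edgeR) and -3.01 for LOC101906766 (adjusted p = 0.0743). LOC101906766 lay at 5.36 log2 CPM in that library and at 5.16 in the highest other one, so that its fold change rested less on it. The lowest other library lay at -2.64, near the floor, and how many animals of each phenotype lay there was not tested. Among other settings limma voom called 0, DESeq2 2 and edgeR without a low-count filter 8. ACAN and MMP11 did not pass by DESeq2 or in the fit to both groups alone. LOC101906766 was the 1 of the 3 genes that passed in each of these. No list passed. The mast cell and basophil list lay 0.28 ± 0.12 higher in resistant animals (p = 0.0267, adjusted p = 0.877 by permutation), with 0 of 11 members called (adjusted over the list alone, 0) and HDC at 0.65 ± 0.22. The B and plasma cell list lay lower (-0.29 ± 0.14, p = 0.0485, adjusted p = 0.877), with 0 of 10 called (adjusted over the list alone, 0) and MZB1 at -1.27 ± 0.45. Adjusted over the list alone, CCL5 (-0.62 ± 0.20) of 11 cytotoxic cell genes, CXCL9 (-1.44 ± 0.42) of 26 interferon genes and BNIP3 (-0.38 ± 0.12) of 16 hypoxia genes were lower in resistant animals. These were not past over the list alone in 12, 4 and 15 of the 39 fits that left out 1 library.

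The response difference, the change in resistant minus the change in susceptible animals, was tested directly. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 0 of 15988 genes passed. At an unadjusted p under 0.05 there were 312, where uniform p-values would give 799. With phenotypes exchanged between animals, 54 of 100 splits, the real one included, reached 312, so that this count is not unusually low. The edgeR fit leaves out the pairing of libraries by animal, and its p-values need not be uniform. With the animal as a block 0 genes passed as well, with 463 at an unadjusted p under 0.05. In other settings DESeq2 called 0, limma voom 0 and edgeR without a low-count filter 1. The genes of smallest p, none of them past, were ACAN (-2.39 ± 0.61 SE), CXCL9 (-2.12 ± 0.60), MMP11 (-1.63 ± 0.47), the T cell checkpoint receptor LAG3 (-0.95 ± 0.30) and the collagen COL8A1 (-1.63 ± 0.52). Without susceptible after replicate 5 the differences were -0.29 for ACAN, -0.09 for MMP11 and -0.52 for COL8A1. CXCL9 went from 2.95 ± 2.74 to 1.80 ± 1.55 CPM (SD, n = 20) in resistant and from 1.85 ± 1.51 to 4.91 ± 7.13 CPM (SD, n = 19) in susceptible animals. None of the 40 lists passed (lowest p = 0.151, adjusted p = 0.982 by permutation), and the lowest p was that of the interferon response list (-0.43 ± 0.29), in which 19 of 26 members were lower adjusted over the list alone and 0 over all genes. Without resistant before replicate 20, 0 were lower over the list alone, as in 3 of the 78 fits that left out 1 library. In simulated data, 41.8% of genes with a 1.5-fold and 80.6% with a 2-fold response difference were recovered by the main test. Libraries were drawn independently there, without an effect of the animal. The real libraries of an animal correlate, so that these shares do not set a detection limit for the real data. Differences of 1.5-fold, and larger ones in genes of wide spread, may have been missed, since CXCL9 did not pass at -2.12 ± 0.60.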

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

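The fits without 1 library in turn and without the 4 libraries least like their groups were chosen after the results had been seen, and every other alternative was planned. Of the 309 results of named genes, none of those fitted in each of the 12 gene-level settings was reversed (309 in most, but 307 with the stricter filter, 286 with the compared groups alone, 267 with the animal block, 41 with the block on the shared number and 42 with a random block), while calls were lost most often with limma voom (34 lost, 3 gained), with sample quality weights (30 lost, 12 gained) and with the compared groups alone (20 lost, 1 gained). DESeq2's size factors ended 0 calls, the stricter filter 1, no filter 9, the DESeq2 test 5, 2 surrogate variables 7 and leaving out the 4 libraries 14, and 56 of the 309 changed call without some single library. In resistant animals after versus before, 3502 genes passed with the animal as a block and 4245 with 2 surrogate variables against 2312, of which 2253 and 2303 were shared with the 2312, and the other settings gave 2194 to 3435. In susceptible animals 3655 passed with 2 surrogate variables and 1455 with both compared groups alone against 2188, of which 2138 and 1431 were shared, and the others gave 1840 to 3188. The fit to the compared groups raised the count in resistant animals (2641), and the cause of these shifts was not tested. Without 1 library the counts ranged from 2012 (without resistant after replicate 15) to 2751 (without resistant after replicate 17) and from 1658 (without susceptible after replicate 6) to 2348 (without susceptible after replicate 15). Between the phenotypes before infestation 3 genes passed with no filter and 2 by DESeq2 against 0 by edgeR, with 1195 at an unadjusted p under 0.05, and 0 passed in each of the 39 fits without 1 library. After infestation 8 passed with no filter against 3, and 1, LOC101906766, in the fit of both groups alone. Then 0 passed by edgeR with 2 surrogate variables (563 at an unadjusted p under 0.05) and without the 4 libraries (1514), by limma voom (538), with quality weights (1316), and with a random block (557). Without 1 library it was 0 (without susceptible after replicate 5) to 4 (without susceptible after replicate 2). For the response difference 1 gene passed with no filter against 0, with 312 at an unadjusted p under 0.05, and 0 passed in each of the 78 fits without 1 library. The animal block also gave 0 genes there, with 463 at an unadjusted p under 0.05. Across phenotypes the animals share only a number, the 19 pairs correlating with a median of -0.0205 before and -0.0897 after and 4 pairs above 0.1 each time. A block on that number gave 0 genes before (380 at an unadjusted p under 0.05) and 0 after (464). Among the 267 results of named genes in the comparisons of time and the response difference, the animal block ended 9 calls and made 14, and it changed no other call of a gene named by the rule. The 4 calls it ended among the members named outside the rule (CCL20, CXCL3 and CXCL9 in susceptible and LYZ2 in resistant animals) stand with the results. It ended 1 of 45 list calls (skeletal muscle) and changed no other list call. DESeq2's size factors ended 1 of the 45 (basal keratinocyte). With the median of members 28 list tests passed, with 20 calls lost, 4 gained and 1 reversed, the skeletal muscle list in resistant animals at 0.0105 against -0.18. With an estimated correlation 0 passed (lowest adjusted p = 0.216), a test against the other genes in place of a test against 0 shift. The correlation of both responses was 0.804 with the stricter filter and 0.80 with DESeq2's size factors against 0.801. Response differences of 1.5-fold were recovered for 41.8% of genes simulated without an effect of the animal. Such simulated shares set no detection limit for the real data. Differences of that size, and larger ones in genes of wide spread, may have been missed, since CXCL9 did not pass at -2.12 ± 0.60 (log2, SE).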

Other observations

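All tests of explanations and all other splits of the samples given here were chosen after the results had been seen, and the gene lists and their tests were planned.

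Genes of sebaceous lipid metabolism moved both ways after infestation, with no shift of the list as a whole (-0.01 ± 0.07 SE in resistant and -0.01 ± 0.08 in susceptible animals, adjusted p = 0.862 and 0.957 by permutation). In resistant animals 4 of 21 members rose and 3 fell by edgeR (adjusted over the list alone, 4 and 6). The lipoxygenase ALOX15B rose 2.40-fold, the acyltransferase gene DGAT2L6 rose 1.72-fold and SOAT1, which forms cholesterol esters, rose 1.54-fold, while the fatty acid desaturase FADS2 fell by 0.98 ± 0.19 on the log2 scale. In susceptible animals 2 rose and 3 fell (adjusted over the list alone, 3 and 4), with ALOX15B at 2.00-fold and FADS2 at -0.84 ± 0.19. THRSP and MGST1, which also fell there, did not pass without susceptible before replicate 2 (-0.46, adjusted p = 0.12, and -0.34, adjusted p = 0.0876, by edgeR).

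Some immediate early genes, which are transcribed within minutes of a stimulus, were lower 24 h after infestation. In resistant animals 5 of 20 fell and 0 rose by edgeR (adjusted over the list alone, 5 and 0). FOSB fell by 1.68 ± 0.44 and KLF4 by 0.61 ± 0.12 on the log2 scale, and NR4A2 (-0.55 ± 0.17) and DUSP1 (-0.48 ± 0.15) also fell. NR4A2 did not pass without resistant before replicate 15 (-0.38, adjusted p = 0.0935), nor DUSP1 without resistant before replicate 1 (-0.41, adjusted p = 0.0557), nor FOSB by limma voom (-1.11, adjusted p = 0.0599). In susceptible animals 3 fell (adjusted over the list alone, 1 higher and 3 lower), among them KLF4 (-0.55 ± 0.13) and FOSB (-1.70 ± 0.45), the latter not past without susceptible before replicate 14 (-0.70, adjusted p = 0.225 by edgeR). The list as a whole did not shift (-0.11 ± 0.12 SE, adjusted p = 0.44, and -0.02 ± 0.13, adjusted p = 0.957, by permutation). Of the cornified barrier genes in resistant animals, loricrin, LOR, fell by 0.93 ± 0.24 and 1 of 17 members rose and 3 fell (adjusted over the list alone, 1 and 4). In susceptible animals 1 rose and 0 fell (adjusted over the list alone, 1 and 0). The list score was nonetheless higher after infestation in 6 of 20 resistant and 6 of 19 susceptible animals. Its SD in susceptible animals was 0.899 before and 0.336 after, and the list was not tested without susceptible before replicate 2, which stood apart from its group.

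The change from before to after infestation spread widely over the animals. Each animal gave 1 biopsy per time, so that a difference between animals cannot be told apart from one between biopsies. This limit also holds for the relations between lists, which were scored in the same biopsies. After minus before, the matrix remodelling list moved by -0.40 to 1.66 in resistant animals and by -0.30 to 2.13 in susceptible animals, in log2 CPM. Across animals it was related to the neutrophil list in resistant (Pearson r = 0.752, p = 0.00013, adjusted p = 0.0006, Spearman rho = 0.681, p = 0.00132, adjusted p = 0.00528, n = 20) and susceptible animals (r = 0.706, p = 0.00081, adjusted p = 0.00243, rho = 0.642, p = 0.00369, adjusted p = 0.0111, n = 19). These are permutation tests over 12 relations, and MMP9 stands in both lists. Without the 2 animals farthest from the median r was 0.607 and 0.758. For the dendritic cell list r was 0.787 (p = 9e-05, rho = 0.698, p = 0.0009) and 0.77 (p = 0.00015, rho = 0.795, p = 0.00012), all with adjusted p of at most 0.00528 by permutation, and 0.626 and 0.831 without those 2. For activated keratinocytes r was 0.563 (adjusted p = 0.0183) and 0.615 (adjusted p = 0.0132) by permutation, and 0.519 and 0.673 without those 2. The mast cell and eosinophil lists had r from 0.219 to 0.425 with none past (lowest adjusted p = 0.0934), although Spearman's rho passed for mast cells in susceptible animals (0.549, adjusted p = 0.0234). The relation to the interferon list in resistant animals (0.551, adjusted p = 0.0282) rests on the 2 farthest animals, without which r was 0.0652, whereas in susceptible animals it was 0.558 (adjusted p = 0.0192) and 0.464 without them.

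Chance was tested for the number of genes called, not for each gene, and is unlikely to account for that number within each phenotype. With before and after exchanged within animals, only the real one of 100 splits reached 2312 genes in resistant animals (highest other 102), and only the real one of 100 reached 2188 in susceptible animals (highest other 61). With libraries exchanged freely in 50 splits the highest others were 140 and 6. Chance cannot be excluded for the comparisons of phenotypes. After infestation 30 of 100 splits reached the real count of 3 genes (highest other 41). For the comparison before infestation and the response difference the real count was 0, which all 100 splits reach by construction (highest others 624 and 1). There the number of genes at an unadjusted p under 0.05, 1195 and 312, was reached by 37 and 54 of 100 splits (highest others 4038 and 1582). Why 1 split called 624 genes was not tested.

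In resistant animals 18 of 26 interferon response genes were called lower by edgeR, but the list did not pass (-0.40 ± 0.25 SE, adjusted p = 0.168 by permutation), the list was lower in 15 of 20 animals with a median of -0.102, and 3 members were called with the animal as a block and 3 by limma voom. Only 5 members were called without resistant before replicate 20, a library with a list score of 7.2 against 5.83 for the next highest and a median of 3.56 in its group. The median score of resistant animals after infestation was 3.55. That library may be the source of many of the calls but not of all, since RSAD2 (2.29-fold, adjusted p = 0.00259), ISG15 (2.74-fold, adjusted p = 0.00897) and IFI6 (1.82-fold, adjusted p = 0.0343) were lower by edgeR without it, and resistant before replicates 11 and 9 also scored 5.83 and 5.64. ISG15 was higher after infestation in 10 of 20 resistant animals, and it did not pass with the animal as a block (adjusted p = 0.236 by edgeR). The response difference between the phenotypes for the list gave p = 0.151 by permutation (-0.43 ± 0.29 SE), which decides nothing. In susceptible animals the median change of the list was -0.142, against -0.102 in resistant animals, and 9 of 19 susceptible animals lay above 0. A fall in further animals stays open, and an infection or another exposure before infestation was not tested.

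The smooth muscle list (6 of 10 members lower in each phenotype) and the nerve list (6 of 12 in resistant and 4 of 12 in susceptible animals) fell by permutation but did not pass with an estimated correlation (adjusted p = 0.284 and 0.228, and 0.258 and 0.216), and a candidate explanation is less dermis in the second biopsies. Over 39 animals smooth muscle fell by more than the mean of the fibroblast and endothelium lists (difference -0.284 ± 0.0882 SE, p = 0.00209 by permutation), but each of these lists was itself higher after infestation in only 6 of 20 resistant and 6 of 19 susceptible animals, and COL1A1 and COL1A2 fell in resistant animals. The difference was -0.203 ± 0.111 SE for smooth muscle and -0.155 ± 0.0971 for nerve in resistant animals, within 2 SE of 0 (but not against endothelium alone, -0.257 ± 0.088 and -0.209 ± 0.0831), and -0.369 ± 0.139 and -0.287 ± 0.119 in susceptible animals, where without replicate 5 it was within 2 SE of 0 against the fibroblast list alone (-0.293 ± 0.154 and -0.205 ± 0.116), so that less dermis cannot be told apart from a change of these cell types. The clock list was lower in the same biopsies (-0.298 ± 0.0471 SE, below 0 in 33 of 39 animals), with 8 and 6 of 17 members called lower and NFIL3 higher. Its call was lost with the median of members (adjusted p = 0.103 and 0.363 by permutation). By camera with an estimated correlation, against all other genes, it did not pass (adjusted p = 0.258 and 0.216). An effect of the time of day or of handling at the second biopsy cannot be told apart from one of the larvae either, since every library from after infestation is a second biopsy.

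ACAN and MMP11 were lower in resistant animals after infestation through 1 library. Susceptible after replicate 5 had a fibroblast and matrix score of 11.4, which is 4.78 SD above the mean of the other libraries (8.97, SD 0.504, highest other 9.99), and neither gene passed without it. A biopsy rich in matrix transcripts may account for these calls. A smaller phenotype difference cannot be told apart from none, with ACAN at -0.226 (log2, resistant minus susceptible) without that library.

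Among genes tested, 3 were below 0.5 CPM in both libraries of 3 to 20 animals and, in both libraries of all others, at least 1 CPM and more than 4 times the highest value of the low animals (taken as at least 0.1 CPM). These limits and genes were chosen after the data had been seen. SYT4 was at most 0.09 CPM in 4 animals and at least 9.14 CPM in 35, BOLA-DQA2 at most 0.377 CPM in 6 and at least 12.4 CPM in 33, and IL32 at most 0.397 CPM in 5 and at least 2.02 CPM in 34. Between phenotypes the low animals numbered 2 resistant and 2 susceptible for SYT4 (p = 1), 2 and 4 for BOLA-DQA2 (p = 0.407) and 4 and 1 for IL32 (p = 0.342), by Fisher's exact test. These exact tests have few low animals, and the p-values do not show that the phenotypes are alike.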
